A study of Mus musculus with 8 samples.

How the data were processed

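The series measured gene expression by RNA sequencing in bone marrow cells of C57BL/6J mice. Per the labels, the cells were Flt3- LSK cells, a bone marrow fraction that holds haematopoietic stem cells and early progenitors, and 24000 of them were sorted for each sample. WT samples carried floxed Runx1, and samples labelled Mut were described as Runx1 deficient. Runx1 encodes a transcription factor of blood cell development. Per the labels, ERCC spike-in RNA, a set of synthetic transcripts, was added to the purified RNA, and 2 kinds of library were then made. One kind was made from polyA-selected RNA (here mRNA libraries) and the other from total RNA, in order to compare ribosomal RNA (rRNA). Each kind had 2 WT and 2 Mut-labelled libraries, so that 8 libraries were analysed. Libraries with the same name in both kinds were read as parts of 1 sorted sample.

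The deposited table held raw counts, whole numbers that had not been normalised, with 1 column per library. Per the submitters' processing notes, the genome build was mm9 and the tools were TopHat, featureCounts and edgeR, with no version, role or order. The annotation release, the counting of multiply mapped reads and the use of strand are not given in the sources used here. Reads shared between near-identical genes, such as immunoglobulin variable genes, ribosomal protein pseudogenes and histone genes, and reads of overlapping genes may therefore be split or lost, and values of such genes are uncertain. The table had 38086 entries, of which 37991 were gene identifiers, 92 were ERCC transcripts and 3 were rRNA species (28S, 18S and 5.8S). Gene symbols were taken from a GENCODE M21 name table, which matched 32919 identifiers. The other 5072 identifiers had no symbol there and were tested but not named. That table was used for names alone, and no coordinates are given.

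Counts assigned to genes ranged from 35096252 to 37924699 in the mRNA libraries and from 967694 to 1218437 in the total RNA libraries, in which rRNA took 93.3 to 94.5% of all counts. ERCC and rRNA counts were left out of library totals and of the gene tests. The lower depth of the total RNA libraries left 10546 genes to test there, against 17128 in the mRNA libraries. Intervals and floors given for counts cover counting error only, because reads without molecular identifiers are not independent molecules.

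Groups were compared with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the tool's own filter on low counts, its quasi-likelihood test (two-sided) and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The WT and Mut-labelled libraries were compared within each kind of library with no block, and the dependence of the difference on the kind of library was tested as an interaction over all 8 libraries. Fold changes are log2 values of Mut-labelled over WT, and values per library are CPM, counts scaled to an equal library size, after TMM scaling. A fold against a group with 0 counts is a lower bound from a floor of 3 counts per library. Nothing in the labels says that the 2 samples of a group came from separate animals, so that p-values measure only the spread between these samples, which may be technical. The libraries of a group were checked for repeated deposits. Their counts differed far beyond sampling noise, with a chi-square per degree of freedom of 69.2 and 64.6 for WT and Mut-labelled mRNA libraries and 3.17 and 2.76 for total RNA libraries.

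The following 34 gene lists were fixed before the data were examined. Besides the Runx family, cytoplasmic ribosomal proteins, ribosome biogenesis factors and RNA polymerase I machinery were chosen for the subject of the series. Lists on growth were translation factors, mitochondrial ribosomal proteins, MYC-responsive genes, the MYC network and cell cycle genes. Lists on stress were p53 targets, the unfolded protein response and apoptosis regulators. Lineage lists were stem cell associated (HSC), early lymphoid, granulocyte-monocyte progenitor, erythroid, megakaryocyte, and mast cell with basophil and eosinophil genes. Further lineage lists were mature neutrophil, macrophage with dendritic cell, B cell, T cell, NK cell, and stromal genes. Other lists were NF-kB, interferon-responsive, immediate early, nuclear oxidative phosphorylation, mitochondrially encoded, glycolysis, proteasome, histone, and small nucleolar and nuclear RNA genes. The last held genes with published RUNX1 regulation. Mitochondrially encoded genes included rRNA and tRNA genes and were not oxidative phosphorylation genes alone. Lists with at least 5 tested members were tested with camera (limma 3.58.1), which compares a list with the other genes, at a preset correlation of 0.01 and with adjustment over the lists. Camera with an estimated correlation and fry, which does not compare a list with other genes, were alternatives. With an estimated correlation camera tests on the 2 residual degrees of freedom of a comparison, so few lists can pass. A call lost there need not come from correlation between genes. With ERCC scaling lists were tested by fry alone, whose direction can turn when all genes shift. Named genes followed a rule fixed at the same time. It took Runx1 and its family, the 12 largest called changes each way in mRNA libraries and 6 each way in total RNA libraries (mean log2 CPM of at least 3, no overlap between groups), and up to 4 called members per list, or the 2 most abundant where none was called. Genes outside this rule were named after their values were seen, and each such name is given as that or belongs to a fixed list.

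Endogenous and rRNA counts were divided by ERCC counts in each library, and ratios of group means were compared with a two-sided exact permutation test, which cannot go below p = 0.333 with 2 against 2. The amount of spike-in per cell is not given in the sources used here. Alternatives were other scalings (RLE, upper quartile, library totals, ERCC counts), no filter and a stricter filter (CPM of at least 5 in 2 libraries), DESeq2 1.42.0, limma-voom, edgeR's exact test, 1 fit over all libraries, each library left out in turn, the replicate number as a block, removal of mitochondrially encoded genes, and other thresholds. Leaving out 1 library leaves 1 in its group, which is then assumed to vary like the other group. Removal of immunoglobulin genes, removal of genes that follow epithelial transcripts (log2 total RNA over mRNA level of at least 1 in WT and an interaction of at most -0.5, a choice made on the difference between the kinds itself), and ERCC scaling combined with the block were added after seeing the data. Figures were drawn with matplotlib 3.10.9.

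The tests were checked on simulated counts for the same genes and library sizes. In the simulated mRNA comparison (17128 genes), 26.9% of genes changed 2-fold, 67.2% changed 4-fold and 78.8% changed 8-fold were recovered. In the total RNA comparison (10546 genes) these shares were 53.7%, 91.0% and 90.9%. In the interaction (17416 genes) they were 5.97%, 43.3% and 59.1%. False calls exceeded the nominal 5%: 22 of 137 calls in the simulated mRNA comparison, 19 of 181 in total RNA and 9 of 81 in the interaction were unchanged genes. In simulations of the list test, a list of 40 genes shifted 1.5-fold was called in both kinds of library, and 0 of 40 unshifted lists were. Simulated genes varied independently, so false list calls under correlation between genes were not checked. Estimated correlations of the real lists in mRNA libraries ranged from -0.135 (Runx family) to 0.980 (mature neutrophil genes).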

Results

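RNA was measured in Flt3- LSK cells, the bone marrow fraction that holds haematopoietic stem cells and early progenitors, from C57BL/6J mice labelled WT and Mut, the latter described in the labels as Runx1 deficient. There were 2 WT and 2 Mut-labelled samples, each of 24000 sorted cells. By its name each was read as measured in an mRNA and a total RNA library. Gene counts of WT replicates 1 and 2 and Mut-labelled replicates 1 and 2 were 37441941, 37924699, 35096252 and 37311315 in the mRNA libraries. In the total RNA libraries they were 1037573, 1001792, 967694 and 1218437, next to 17666956 to 18511849 counts of all kinds. The title of the series concerns ribosome biogenesis, and its design text names the comparison of WT with Runx1-deficient cells.

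Runx1 itself (ENSMUSG00000022952), which encodes a transcription factor of blood cell development, was higher in the libraries labelled Mut. In the mRNA libraries its level was 204 ± 5.34 CPM in WT and 845 ± 136 CPM in Mut-labelled libraries (SD, n = 2 each), a log2 fold change of 2.05 (SE 0.18, edgeR adjusted p = 0.00753). In the total RNA libraries it was 236 ± 4.37 and 865 ± 57.7 CPM (SD, n = 2 each), a log2 fold change of 1.88 (SE 0.16, edgeR adjusted p = 5.6e-07). Under ERCC scaling Runx1 stood at 1.73 (edgeR adjusted p = 0.999) and 0.78 (edgeR adjusted p = 0.257), and Runx3 in total RNA libraries turned to -0.47. This direction goes against the label. The labels do not give the deleted part of the gene, and a count over the whole gene cannot check a deletion within it, so groups are called Mut-labelled throughout and every direction rests on the labels. Of the other Runx family members, which encode related factors and their partner, Runx3 had log2 fold changes of 0.63 in mRNA libraries (adjusted p = 0.0764) and 0.58 in total RNA libraries (edgeR adjusted p = 0.0487, and 0.347, 0.182 and 0.0788 without WT replicate 1, Mut-labelled replicate 1 and Mut-labelled replicate 2). Runx2 (0.40) and Cbfb (0.17) did not pass in mRNA libraries (edgeR adjusted p = 0.212 and 0.742), nor did Runx1t1, the 1 member with a negative change. Runx1t1 was in the list but is not itself a Runx factor. The list had a median of 0.40 and a mean of 0.24 there. Adjusted over the list alone, 3 of the 5 members were higher in mRNA libraries. The family as a list was called higher there by camera (adjusted p = 0.0021). Under ERCC scaling it was tested with fry alone, which pointed down. It was not called with an estimated correlation (adjusted p = 0.529), without WT replicate 1 (adjusted p = 0.0593) or without Mut-labelled replicate 1 (adjusted p = 0.0528).

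**Figure D1:**
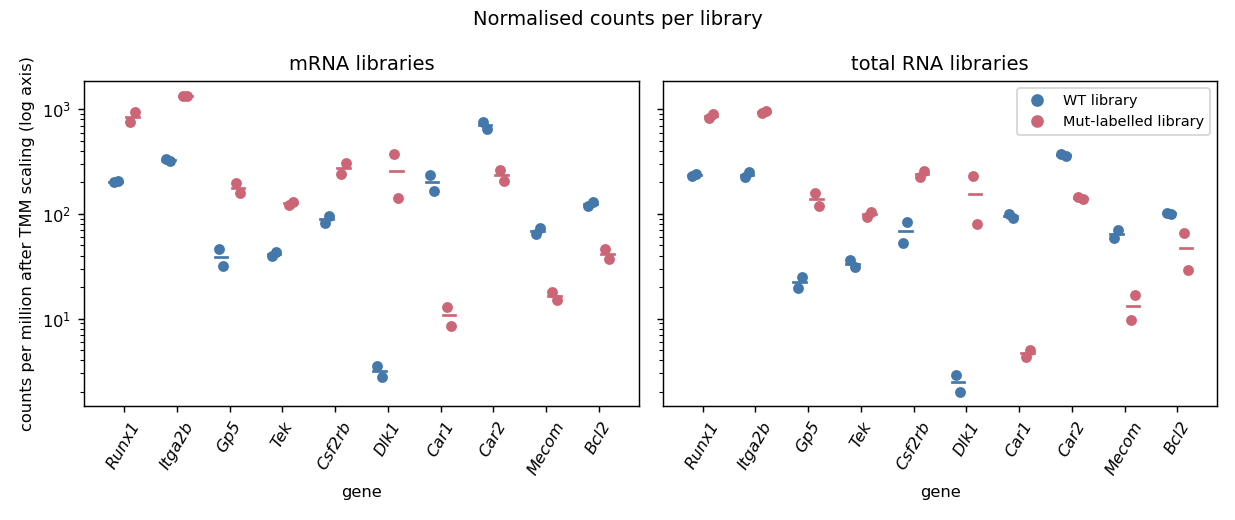
CPM after TMM scaling (log axis) of 10 genes in each library, with mRNA libraries on the left and total RNA libraries on the right; points are libraries and bars are group means (n = 2). Runx1 lay at 200 and 208 CPM in the WT mRNA libraries and at 749 and 941 CPM in the Mut-labelled ones.

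In the mRNA libraries, 7 of 17 genes of platelets and their precursors rose in the Mut-labelled samples and 1 fell, and 6 of 15 genes of the red cell lineage fell. As lists, neither was called with an estimated correlation (camera adjusted p = 0.529 and 0.661). Itga2b, the integrin subunit of the platelet fibrinogen receptor, rose from 327 ± 13.4 to 1345 ± 0.795 CPM (SD, n = 2 each), a 4.11-fold change. Car2, a carbonic anhydrase of red cell precursors, fell from 702 ± 85.7 to 235 ± 43.1 CPM (SD, n = 2 each). The mast cell protease gene Cpa3 rose 20.1-fold and Dlk1, which encodes a membrane protein related to Notch ligands, rose 81.2-fold. Mecom, a transcription factor gene needed to maintain haematopoietic stem cells, fell by 2.06 on the log2 scale.

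Of 17128 genes tested in the mRNA libraries, 624 were called, 300 higher and 324 lower in Mut-labelled samples, and 2682 had an unadjusted p below 0.05. The calls included 22 identifiers without a symbol. The median change of all genes was -0.01 on the log2 scale under TMM, so that changes are relative to the other genes of a library. Scaling by ERCC counts moved that median to -0.38 and gave 170 calls, 16 higher and 154 lower, of which 80 were among the 624. The largest called rises among abundant genes were those of Dlk1 (log2 fold change 6.34, SE 0.55), the myeloid receptor genes Cd200r4 (5.37) and Cd200r3 (5.33), She (4.66), the platelet receptor gene Clec1b (4.49), Cpa3 (4.33), the transcription factor gene Sox5 (4.30), Slc35d3 (4.26), Qrfp (4.08), Zfp711 (3.98) and the phosphatase gene Ppm1e (3.94). Nrg3, a growth factor gene, had 2 counts in the WT libraries together and 1089 and 610 counts in the Mut-labelled libraries. That is a ratio of 905 with a 95% counting interval of 250 to 7475.

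The largest called falls held 4 immunoglobulin variable genes, which encode the antigen-binding parts of antibodies and are made by B and plasma cells. Igkv4-90 had 0 counts in both Mut-labelled mRNA libraries and 229 and 1184 in the WT libraries, which makes it at least 221-fold lower. Igkv5-39 had 1 count against 275 and 2359, a WT over Mut-labelled ratio of 2474 (95% counting interval 444 to 97747). Igkv2-137 had 2 counts against 215 and 2015, a ratio of 1047 (interval 290 to 8652), and Ighv6-6 had a log2 fold change of -6.96. The calls of Igkv5-39 and Igkv2-137 were lost without Mut-labelled replicate 2 (adjusted p = 0.0508 and 0.062). Immunoglobulin transcripts differed widely within groups: Igkc, the kappa constant gene, chosen after its values were seen, stood at 592 and 6735 CPM in the WT and 268 and 1391 CPM in the Mut-labelled mRNA libraries. The basophil protease gene Prss34 had 1 count in the Mut-labelled libraries together and 2614 and 1693 in the WT libraries, a ratio of 4045 (interval 726 to 159809). The other large falls were those of Cdcp1 (log2 fold change -7.10), Myl10 (-5.64), Serpinf1 (-5.41), the carbonic anhydrase gene Car1 (-4.23), Dkkl1 (-4.18), the B cell receptor gene Cd72 (-3.98) and the adenylate kinase gene Ak4 (-3.96).

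Among the lineage lists, 7 of 17 megakaryocyte genes were called higher and 1 lower, and 10 and 1 adjusted over the list alone, with a median log2 fold change of 1.24. Treml1, a platelet granule receptor gene, rose by 3.74, Itga2b by 2.04 and Gp5, a platelet glycoprotein gene, by 2.18 on the log2 scale, while Vwf, the clotting factor that platelets carry, fell by 1.31. Of 15 erythroid genes, 6 were called lower and 0 higher by edgeR, with 9 at an unadjusted p below 0.05 and 9 lower adjusted over the list alone. Their median was -1.58. Car1 fell 18.8-fold, Ank1, a red cell membrane skeleton gene, fell by 1.85, Ermap fell by 2.18 on the log2 scale, and Klf1, the red cell transcription factor gene, fell 4.0-fold. Gata1, a transcription factor gene of both lineages, had a log2 fold change of -0.09 (adjusted p = 0.913). Camera called the megakaryocyte list higher (adjusted p = 7.5e-15) and the erythroid list lower (adjusted p = 2.2e-13), under ERCC scaling with fry in the same directions. With an estimated correlation these were 0.529 and 0.661.

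Of 26 HSC-associated genes, 2 were called higher and 5 lower (4 and 9 adjusted over the list alone), with a median of -0.24. Besides Mecom, Ndn, a growth suppressor gene (log2 fold change -4.89), Prdm16, a transcription factor gene of stem cell maintenance (-1.49), and Procr, the protein C receptor gene used as a stem cell marker (-2.13), fell. Tek, which encodes the angiopoietin receptor of stem and endothelial cells, rose by 1.62, and the adhesion molecule gene Esam by 0.86. The list was called lower (camera adjusted p = 0.021), but not with an estimated correlation (adjusted p = 0.692) nor without WT replicate 2 (0.0831), Mut-labelled replicate 1 (0.0969) or Mut-labelled replicate 2 (0.0635). Of 16 granulocyte-monocyte progenitor genes, 2 were called higher (6 adjusted over the list alone), namely the cytokine receptor genes Csf2rb (3.07-fold) and Csf3r (2.0-fold). Csf3r lost its call without WT replicate 1, WT replicate 2 or Mut-labelled replicate 2 (adjusted p = 0.165, 0.0616 and 0.0681). This list was called higher (camera adjusted p = 0.0165), while fry pointed down under ERCC scaling. Its call was lost with an estimated correlation (camera adjusted p = 0.661), without WT replicate 2 and without Mut-labelled replicate 1. Of 11 mast cell, basophil and eosinophil genes, 3 rose and 3 fell (4 and 7 adjusted over the list alone). Cpa3, Il1rl1, the interleukin-33 receptor gene (log2 fold change 3.19), and Hdc, which makes histamine (1.79), rose, while Prss34, the basophil protease gene Mcpt8 (-3.22) and the eosinophil granule gene Prg2 (-2.03) fell. Its median was -1.96, the same with 1 gene at its bound, and the list was not called (camera adjusted p = 0.49), except as lower without WT replicate 2 (0.00847).

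**Figure D2:**
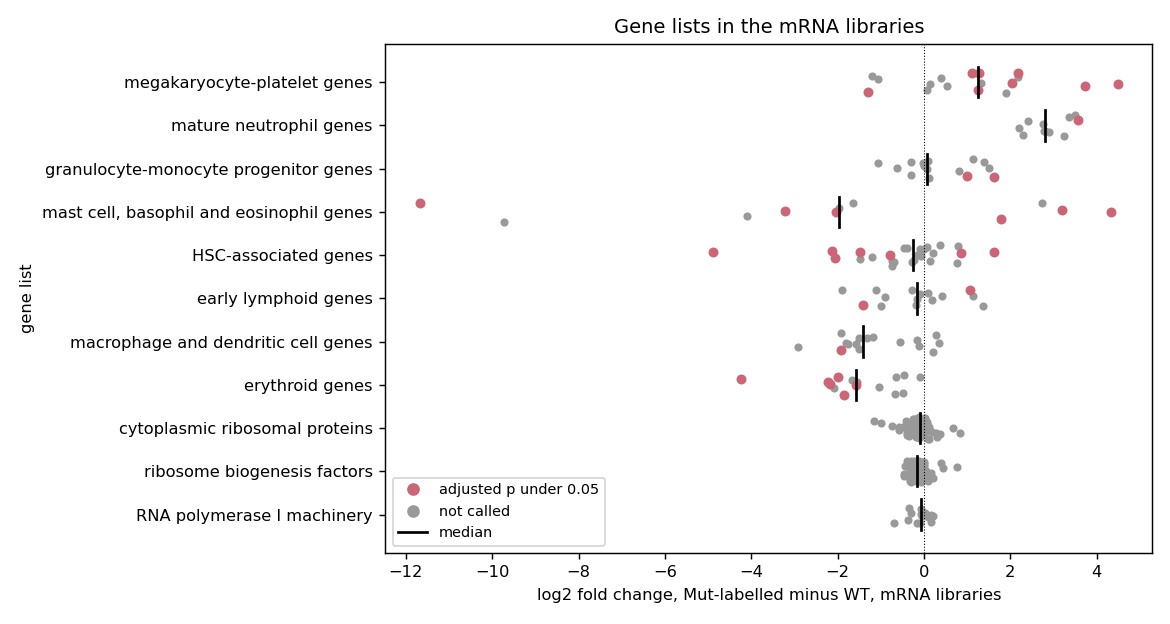
Log2 fold changes (Mut-labelled minus WT, mRNA libraries) of the tested members of 11 gene lists; red points passed an adjusted p under 0.05, grey points did not, and black bars are medians. The megakaryocyte median was 1.24 and the erythroid median -1.58.

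Markers of mature blood cells and of stromal cells also differed, although a lineage-negative sort such as LSK is meant to remove mature blood cells. All 11 tested mature neutrophil genes were higher, with a median of 2.80. Of these 1 was called, Retnlg, a resistin-like gene of neutrophils (log2 fold change 3.56), while 11 passed adjusted over the list alone (camera adjusted p = 3.6e-11, and 0.661 with an estimated correlation). Their summed level was 40.3 and 49.5 CPM in the WT libraries and 538 and 142 CPM in Mut-labelled replicates 1 and 2. Of 16 macrophage and dendritic cell genes, 1 was called lower, the antigen presentation gene H2-Aa (-1.93), and 6 adjusted over the list alone. The median was -1.41, and the list was called lower (camera adjusted p = 0.0053), but not with an estimated correlation (adjusted p = 0.529) nor without Mut-labelled replicate 2 (adjusted p = 0.0511). In the T cell list the kinase gene Lck fell by 3.21 and the adaptor gene Lat rose by 1.45 (median -0.51, 1 up and 2 down adjusted over the list alone, camera adjusted p = 0.655, turned up without Mut-labelled replicate 2 at 0.832). In the stromal and endothelial list the matrix gene Bgn fell by 2.78 and the endothelial receptor gene Kdr rose by 2.89 (median -0.83, camera adjusted p = 0.262, and 4.7e-04 without Mut-labelled replicate 1 and 0.0208 without WT replicate 2). In the early lymphoid list Notch1, a receptor gene of T lineage choice, fell by 1.40 (median -0.17, camera adjusted p = 0.749, turned up without Mut-labelled replicate 1 at 0.895). Of 8 NK cell genes, Nkg7, a granule protein gene, was lower (-1.36). The median of that list was 0.71 while its mean was -0.17 and camera pointed down (adjusted p = 0.326, and 0.0239 without Mut-labelled replicate 1), but up without Mut-labelled replicate 2 (0.363). No B cell gene of 8 was called by edgeR (1 at an unadjusted p below 0.05; Cd79b 0.03; camera adjusted p = 0.927, turned down without WT replicate 2 at 0.905 and Mut-labelled replicate 1 at 0.242).

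For the lists on ribosomes and growth, 0 of 78 cytoplasmic ribosomal protein genes were called by edgeR in mRNA libraries, with 2 at an unadjusted p below 0.05. Their median log2 fold change was -0.09, 24 were positive and 54 negative, and Rps3 (0.07) and Rpl4 (0.01) were the most abundant. Camera did not call the list (adjusted p = 0.48), but called it lower without WT replicate 2 (adjusted p = 4.9e-04) or Mut-labelled replicate 1 (0.0036) and turned its direction without WT replicate 1 (0.362) or Mut-labelled replicate 2 (0.363). Of 108 ribosome biogenesis factors, 0 were called by edgeR, 5 had an unadjusted p below 0.05, and 96 were negative, with a median of -0.17. The most abundant, the nucleolar protein genes Ncl and Mybbp1a, had log2 fold changes of -0.22 and -0.20. Camera called this list lower (adjusted p = 0.0253), with an adjusted p = 0.976 with an estimated correlation, 0.633 without WT replicate 1 and 0.171 without Mut-labelled replicate 2. The RNA polymerase I machinery, which transcribes rRNA genes, had 0 of 14 called by edgeR and 2 at an unadjusted p below 0.05 (median -0.08, camera adjusted p = 0.49). Its members Ubtf and Polr1a stood at -0.04 and -0.37. Of 22 MYC-responsive genes 21 were negative and 0 were called by edgeR, with 2 at an unadjusted p below 0.05 (median -0.27). This list was called lower by camera (adjusted p = 0.0295), with an adjusted p = 0.976 with an estimated correlation, 0.599 without WT replicate 1 and 0.54 without Mut-labelled replicate 2. Translation factors (median -0.07, adjusted p = 0.696), mitochondrial ribosomal proteins (-0.14, 0.179), the MYC network (0.16, 0.49), cell cycle genes (-0.03, 0.978), glycolysis (-0.14, 0.933), the proteasome (-0.09, 0.599), mitochondrially encoded genes (-0.23, 0.36) and small nucleolar and nuclear RNA genes (-0.04, 0.933) were not called as lists by camera in the mRNA libraries. Nuclear oxidative phosphorylation genes had a median of -0.14 (adjusted p = 0.138), and 1 of 79, Cox6b2, fell by 1.87. Camera called oxidative phosphorylation genes, mitochondrial ribosomal proteins, the proteasome and mitochondrially encoded genes lower without WT replicate 2 (adjusted p = 2.7e-06, 2.2e-05, 0.0135 and 0.0382) and without Mut-labelled replicate 1 (6.5e-06, 4.7e-04, 0.00286 and 0.00768). The first 3 of these turned up without WT replicate 1 (0.587, 0.692 and 0.492) and without Mut-labelled replicate 2 (0.255, 0.643 and 0.126). So did translation factors (0.602 and 0.602), cell cycle genes (0.551 and 0.0511) and glycolysis (0.692 and 0.602).

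Lists of signalling and stress responses were also called. Camera called NF-kB and TLR genes (median 0.43, adjusted p = 0.0058), immediate early genes (0.44, adjusted p = 0.0059), p53 targets (0.32, adjusted p = 0.00943) and histones (0.62, adjusted p = 0.0073) higher. With an estimated correlation their adjusted p was 0.529, 0.812, 0.529 and 0.826, and fry pointed down for the p53 targets under ERCC scaling. The immediate early list was not called without WT replicate 1 (adjusted p = 0.174). In the NF-kB list the receptor gene Tlr6 rose 4.0-fold and the chemokine gene Ccl3 fell by 3.25 (5 up and 1 down adjusted over the list alone). Ccl3 lost its call without Mut-labelled replicate 2 (adjusted p = 0.0568). None of the 22 immediate early genes was called by edgeR (0 adjusted over the list alone, 5 at an unadjusted p below 0.05), and Fos and Jun had log2 fold changes of 0.81 and 1.15. Of 26 p53 targets 1 was called (2 adjusted over the list alone), Cdkn1a, a cell cycle inhibitor gene (0.73, adjusted p = 0.0429), and of 41 histone genes 1 was called (0 adjusted over the list alone), Hist1h2ac (2.82-fold, adjusted p = 0.0467). Cdkn1a lost its call when any of the 4 libraries was left out (adjusted p = 0.0724 to 0.176), and Hist1h2ac without any but WT replicate 2 (0.0518 to 0.124). Transcripts of duct-type epithelium, a list written after the values were seen, were 1557 and 1571 CPM in WT and 2513 and 2265 CPM in Mut-labelled mRNA libraries, summed over 18 genes. Without the 380 genes that followed these transcripts, selected for values lower in total RNA than in mRNA comparisons, among them Cdkn1a and Hist1h2ac, 567 genes were called, 271 higher and 296 lower, and the p53 targets (adjusted p = 0.0611) and histones (0.0939) were not called. Apoptosis regulators (median 0.24, camera adjusted p = 0.0987, and 0.0359 without WT replicate 1 and 0.0321 without Mut-labelled replicate 2) included Bcl2, which restrains cell death, at 125 ± 9.07 CPM in WT and 41.4 ± 6.54 CPM in Mut-labelled libraries (SD, n = 2 each), a fall by 1.59. The unfolded protein response list had a median of 0.08 and a mean of -0.04 while camera pointed down (adjusted p = 0.958), or up without WT replicate 2 (0.488) or Mut-labelled replicate 2 (0.185), and Asns, which makes asparagine, fell by 1.84. Interferon-responsive genes were not called as a list (median 0.22, camera adjusted p = 0.0987), but were called higher without WT replicate 1 (0.0462) and Mut-labelled replicate 2 (1.4e-05) and turned down without Mut-labelled replicate 1 (0.715), and Oas2, an antiviral enzyme gene, rose by 1.34. Of 16 genes with published RUNX1 regulation 2 rose and 1 fell (4 and 2 adjusted over the list alone), namely Itga2b, Alox12 (3.24) and Myh10 (-2.65). Their median was 0.07 and their mean -0.34, and camera pointed up (adjusted p = 0.538), or down without WT replicate 2 (0.905) or Mut-labelled replicate 1 (0.691).

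In the mRNA libraries 13 of 34 lists were called by camera, 8 higher and 5 lower. The lower ones came to 11 without WT replicate 2 or Mut-labelled replicate 1, 3 without WT replicate 1 and 1 without Mut-labelled replicate 2, beside 7, 6, 8 and 10 higher ones. With an estimated correlation camera called 0, with 0 at an unadjusted p below 0.05, while fry called 0 in 1 direction, with 6 at an unadjusted p below 0.05, and 14 lists as changed in either direction.

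In the total RNA libraries genes of the platelet and red cell lineages changed as well. Itga2b rose from 238 ± 19.8 to 942 ± 16.8 CPM and Car2 fell from 367 ± 7.5 to 142 ± 3.73 CPM (SD, n = 2 each). Mecom was 4.75-fold lower and Tek, the angiopoietin receptor gene, was 2.95-fold higher. All 5 tested neutrophil genes, which encode granule and antimicrobial proteins, rose, though as a list they were not called with an estimated correlation (camera adjusted p = 0.748).

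Of 10546 genes tested, 445 were called, 268 higher and 177 lower, with 1559 at an unadjusted p below 0.05 (edgeR). Scaling by ERCC counts moved the median of all genes from -0.002 to -1.10 and gave 373 calls, 13 higher and 360 lower, of which 166 were among the 445. DESeq2 called 199 genes, 139 higher and 60 lower. The largest rises were those of Dlk1 (log2 fold change 5.89), Slc35d3 (5.23) and Cpa3 (4.36), together with Cd200r3, Nrg3 and Mmp9, each of which had 1 count in the WT libraries. Mmp9, a neutrophil gelatinase gene, had 20 and 17 counts in the Mut-labelled libraries, a ratio of 35.3 (95% counting interval 5.95 to 1431). For Cd200r3 the ratio was 70.6 (interval 12.3 to 2825) and for Nrg3 it was 43.9 (interval 7.49 to 1770). The largest falls were those of Myl10 and Cdcp1, which had 0 counts in both Mut-labelled libraries and were at least 10.9-fold and at least 8.82-fold lower, and of Car1 (-4.31). Prss34, Dkkl1 and the T cell regulator gene Tox had 1, 1 and 2 counts in the Mut-labelled libraries, with WT over Mut-labelled ratios of 68.1 (interval 11.8 to 2733), 39.8 (6.73 to 1614) and 24.1 (6.31 to 205).

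Of 13 megakaryocyte genes 7 were called higher and 1 lower, the same numbers as adjusted over the list alone, among them Gp5 (2.64), Treml1 (3.13) and the integrin gene Itgb3 (1.31). The list was called higher (median 1.31, camera adjusted p = 1.1e-11, and 0.538 with an estimated correlation), while fry pointed down under ERCC scaling. Of 8 erythroid genes 5 were called lower, and 6 adjusted over the list alone, including Car1, Ermap (-2.32) and Ank1 (-1.92). This list had a median of -1.98 (camera adjusted p = 4.0e-18, and 0.324 with an estimated correlation) and was the only one that fry called in a direction (adjusted p = 0.0411). All 7 tested mast cell, basophil and eosinophil genes were called, 4 higher and 3 lower, with Cpa3, Il1rl1 (2.97), Hdc (1.80) and Ms4a2 (3.45), a mast cell receptor gene, among the rises. Camera called this list higher (median 1.80, adjusted p = 7.9e-04, and 0.748 with an estimated correlation), while fry pointed down under ERCC scaling. All 5 tested neutrophil genes were called higher, among them Lcn2 (2.96), S100a8 (2.77) and Ltf (2.41), with a median of 2.77 (camera adjusted p = 8.1e-09, and 0.748 with an estimated correlation). Their summed level was 15.6 and 19.1 CPM in WT libraries and 180 and 76.3 CPM in Mut-labelled replicates 1 and 2, and without Mut-labelled replicate 1 the adjusted p of Mmp9, Lcn2, S100a8 and Ltf was 0.0617, 0.184, 0.328 and 0.184. Of 22 HSC-associated genes 2 rose and 3 fell (3 and 3 adjusted over the list alone), with Prdm16 at -1.71 and Hlf, a stem cell transcription factor gene, at -0.78 (adjusted p = 0.0105, and 0.137 without WT replicate 2). Their median was -0.03 (camera adjusted p = 0.486, turned up without WT replicate 2 at 0.794). Csf2rb (1.83) and Csf3r (0.90, which turned to -0.20 under ERCC scaling) were the called members of the granulocyte-monocyte progenitor list (median 0.15, camera adjusted p = 0.006). For that list fry pointed down under ERCC scaling, and its call was lost with an estimated correlation (camera adjusted p = 0.748) and without Mut-labelled replicate 1.

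For the ribosome lists, edgeR called 0 of 68 cytoplasmic ribosomal protein genes (3 at an unadjusted p below 0.05, median -0.03, camera adjusted p = 0.571), and camera turned up without WT replicate 1 (adjusted p = 0.802). Of 106 ribosome biogenesis factors 0 were called by edgeR, 5 had an unadjusted p below 0.05 and 74 were negative (median -0.11). Camera called the list lower (adjusted p = 0.0494), with an adjusted p = 0.811 with an estimated correlation, 0.459 without WT replicate 1 and 0.514 without Mut-labelled replicate 2. Ncl and Mybbp1a both stood at -0.14. Of 14 RNA polymerase I genes 0 were called by edgeR and 1 had an unadjusted p below 0.05 (median -0.12, camera adjusted p = 0.392). MYC-responsive genes were called lower as a list (median -0.18, camera adjusted p = 0.0494), with an adjusted p = 0.811 with an estimated correlation, 0.472 without WT replicate 1 and 0.645 without Mut-labelled replicate 2. Nuclear oxidative phosphorylation genes were called lower too (median -0.23, camera adjusted p = 0.006), with 0 of 72 called by edgeR and 10 at an unadjusted p below 0.05. Their adjusted p was 0.811 with an estimated correlation, 0.34 without WT replicate 1 and 0.509 without Mut-labelled replicate 2.

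Among signalling genes, NF-kB targets Socs3, a cytokine signalling inhibitor (log2 fold change 1.91), and Tnfaip3, an NF-kB inhibitor (1.24), rose in total RNA libraries. Jun, an immediate early transcription factor gene (1.10), and the growth inhibitor gene Btg2 (1.47) rose as well. The NF-kB list (median 0.39, camera adjusted p = 0.006) and the immediate early list (0.51, adjusted p = 0.0042, with 5 up adjusted over the list alone) were called higher. Both pointed down with fry under ERCC scaling. They were lost with an estimated correlation (adjusted p = 0.748 and 0.811) and without WT replicate 1 (0.111 and 0.879), and NF-kB also without Mut-labelled replicate 2 (0.0571). Histones were called higher (median 0.16, camera adjusted p = 0.0256), with Hist1h2ac at 0.73. Under ERCC scaling fry pointed down for histones, and Hist1h2ac stood at -0.30. That list was lost with an estimated correlation (adjusted p = 0.811), without WT replicate 1 (0.161) and without Mut-labelled replicate 1 (0.908). Bcl2, which restrains cell death, was called lower (-1.14, edgeR adjusted p = 0.0192, and 0.355 without Mut-labelled replicate 2). Apaf1, a caspase activator gene (0.83), Bcl2l2, a survival gene (1.25), Runx3 and the kinase gene Prkcq (0.86) were called higher. Without WT replicate 1 the edgeR adjusted p of Apaf1 was 0.0933, of Bcl2l2 0.138 and of Hist1h2ac 0.0955. Without WT replicate 2 that of Prkcq was 0.0626, without Mut-labelled replicate 1 those of Bcl2l2, Hist1h2ac and Prkcq were 0.262, 0.207 and 0.108, and without Mut-labelled replicate 2 that of Apaf1 was 0.102. Under ERCC scaling Apaf1 and Prkcq turned to -0.26 and -0.22. Among the 23 p53 targets Btg2 and Apaf1 rose, and the list was not called (median -0.21, camera adjusted p = 0.72, turned up without WT replicate 1 at 0.597). Cdkn1a stood at -0.36 (adjusted p = 0.542). Duct-type epithelial transcripts were 6987 and 4144 CPM in WT and 3875 and 3544 CPM in Mut-labelled total RNA libraries. In a fit without the 380 genes that followed them, more genes than these fell out of the test. It then held 10121 genes, against 10546, of which 434 were called, and the neutrophil list was not tested.

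The remaining lists were not called by camera in total RNA libraries. These were translation factors (median -0.11, adjusted p = 0.23), mitochondrial ribosomal proteins (-0.19, 0.0822), the MYC network (0.09, 0.401), the unfolded protein response (-0.09, 0.448), apoptosis regulators (0.25, 0.0917), cell cycle genes (0.06, 0.401), macrophage and dendritic cell genes (0.18 with a mean of -0.13, 0.907), interferon-responsive genes (0.11, 0.18), mitochondrially encoded genes (-0.02, 0.856), glycolysis (-0.18, 0.332), the proteasome (-0.01, 0.669), small nucleolar and nuclear RNA genes (0.16, 0.378), early lymphoid genes (0.04 while camera pointed down, 0.852) and genes with published RUNX1 regulation (-0.03 while camera pointed up, 0.332). Without Mut-labelled replicate 2 camera called apoptosis regulators (adjusted p = 0.0391), cell cycle genes (0.00352), interferon-responsive genes (0.0236), small nucleolar and nuclear RNA genes (1.7e-04) and genes with published RUNX1 regulation (0.0258) higher. Mitochondrial ribosomal proteins were called lower without WT replicate 2 (0.049995) or Mut-labelled replicate 1 (0.0451). Camera turned down for cell cycle genes without Mut-labelled replicate 1 (0.498), for small nucleolar and nuclear RNA genes without Mut-labelled replicate 1 (0.333) or WT replicate 2 (0.991), and for macrophage genes without WT replicate 1 (0.22) or Mut-labelled replicate 2 (0.646). It turned up for early lymphoid genes without WT replicate 2 (0.84) or Mut-labelled replicate 1 (0.681), and without WT replicate 1 or Mut-labelled replicate 2 for the proteasome (0.541 and 0.598) and mitochondrially encoded genes (0.959 and 0.839). Runx family, B cell, T cell, NK cell and stromal genes had fewer than 5 tested members. In all, 11 of 29 lists were called, 7 higher and 4 lower. The lower ones came to 6 without WT replicate 2 or Mut-labelled replicate 1 and to 1 without WT replicate 1 or Mut-labelled replicate 2, beside 7, 5, 4 and 11 higher ones. With an estimated correlation camera called 0, with 2 at an unadjusted p below 0.05, while fry called 1 in a direction and 9 in either direction.

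The kinds of library were compared to see whether the difference depended on how RNA was selected. Dlk1, Cpa3, Itga2b, Car1 and Mecom changed in the same direction in both kinds. Among 10509 genes tested in both, 160 were called higher in both (256 in mRNA and 267 in total RNA libraries), where 6.50 would be shared by independent lists, and 106 were called lower in both (159 and 177), where 2.68 would be. There were 0 called in opposite directions. Log2 fold changes correlated across genes with a Pearson r of 0.739 and a Spearman rho of 0.498, genes not being independent replicates. Both kinds of library were read as coming from the same sorted samples. The test of the interaction called 0 of 17416 genes with edgeR, with 687 at an unadjusted p below 0.05. With a block per sorted sample, which reads both kinds as parts of 1 sample, it called 111 genes, 4 positive and 107 negative. Of these 96 were among the 380 genes that followed the epithelial transcripts, which had been selected for a negative interaction in these libraries. Epithelial markers, listed after their values were seen, made up 15 of the calls. These counts overlap, since the 18 abundant markers were all among the 380.

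**Figure D3:**
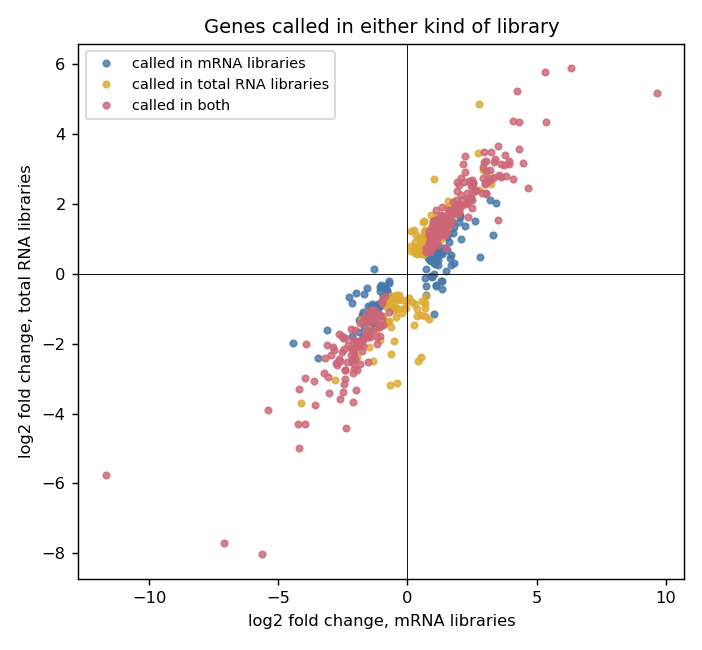
Log2 fold changes (Mut-labelled minus WT) in mRNA libraries (horizontal) and total RNA libraries (vertical) of the 593 genes called in either kind and tested in both; colours show where a gene was called. Across these genes, chosen by their calls, Pearson's r was 0.926, against 0.739 across all 10509 genes tested in both. There were 0 genes called in opposite directions.

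**Figure D4:**
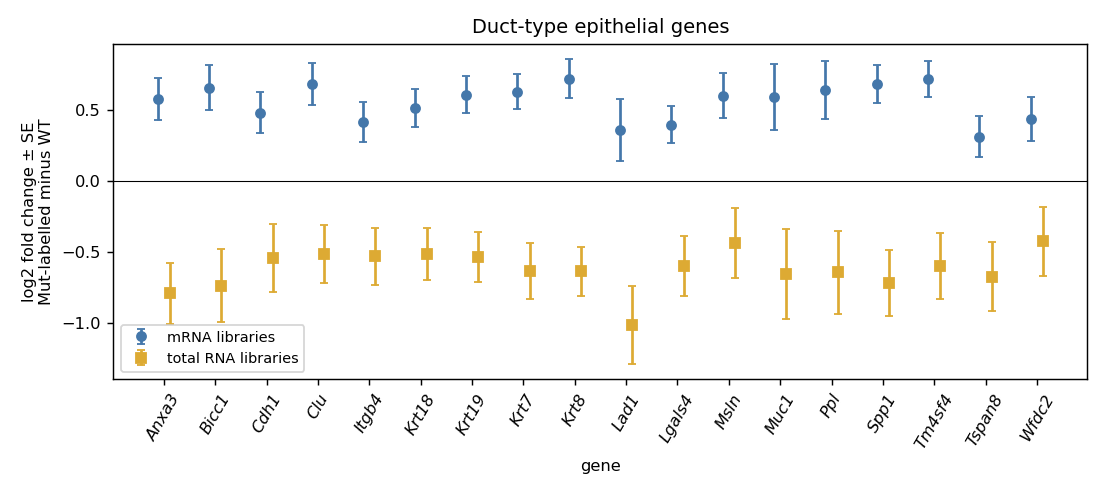
Log2 fold changes with standard errors (Mut-labelled minus WT, n = 2 per group) of 18 abundant duct-type epithelial genes in mRNA libraries (circles) and total RNA libraries (squares). All 18 were positive in mRNA libraries and all 18 negative in total RNA libraries.

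Spike-in RNA was used to compare the amounts of rRNA and of gene transcripts per equal number of sorted cells. It was added to the purified RNA, so it does not correct for RNA lost before that step. Ribosomal RNA, the structural RNA of ribosomes, came to 3513 ± 607 counts per ERCC count in WT and 1637 ± 845 in Mut-labelled total RNA libraries (SD, n = 2 each), a ratio of 0.466 with an exact permutation p of 0.333, the smallest possible with 2 against 2. Leaving out single libraries gave ratios from 0.296 (without Mut-labelled replicate 1) to 0.636 (without Mut-labelled replicate 2). The ERCC counts behind these values were 4293 and 5649 in WT and 7471 and 16620 in Mut-labelled replicates 1 and 2. By species the ratio was 0.460 for 28S, 0.503 for 18S and 0.499 for 5.8S rRNA. Gene transcripts in the same libraries came to 210 ± 45.5 and 101 ± 39.8 counts per ERCC count, a ratio of 0.484 (exact permutation p = 0.333). In both cases each Mut-labelled library lay below each WT library. In the mRNA libraries gene transcripts came to 237 ± 117 and 187 ± 106 counts per ERCC count, a ratio of 0.792 (exact permutation p = 0.667), with ratios of single libraries between 0.351 and 1.71. That ratio was 0.474 without Mut-labelled replicate 2 and moved above 1 without WT replicate 2 (1.22) or Mut-labelled replicate 1 (1.11). Between same-numbered samples, which the labels do not pair, it was 0.730 for replicate 1 and 0.821 for replicate 2. rRNA per gene count was 16.8 ± 0.762 in WT and 15.7 ± 2.17 in Mut-labelled libraries, a ratio of 0.933 (exact permutation p = 0.667). Transcripts of duct-type epithelium are counted in these values as transcripts of the cells.

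**Figure D5:**
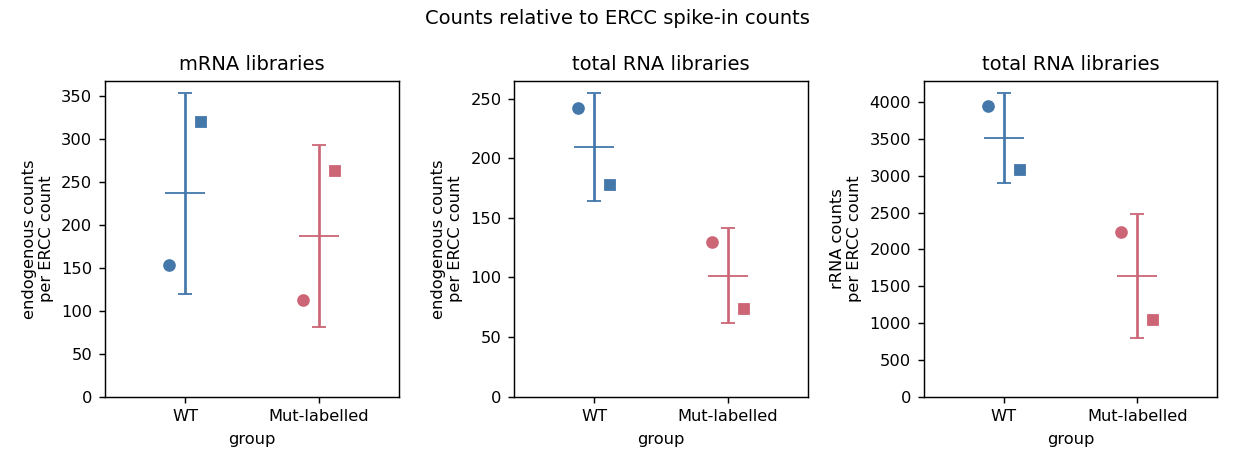
Counts per ERCC count in each library: gene transcripts in mRNA libraries, gene transcripts in total RNA libraries and rRNA in total RNA libraries; points are libraries (circles replicate 1, squares replicate 2), and bars are means ± SD (n = 2). In total RNA libraries the Mut-labelled rRNA values, 2234 and 1040, lay below the WT values, 3942 and 3084.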

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

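A difference between the kinds of library was flagged in duct-type epithelial genes, which encode keratins, mucins and secreted proteins of ducts, and the list and its tests were chosen after the values were seen. Of 29 listed genes 18 were abundant, among them Krt8, Krt18, Krt19, Cdh1, Spp1 and Clu. Their median log2 fold change (Mut-labelled minus WT) was 0.60 in mRNA libraries, where 18 of 18 were positive, and -0.62 in total RNA libraries, where 18 of 18 were negative. Single genes were called in 1 and 3 cases. The fall in total RNA libraries rested mainly on WT replicate 1: summed levels were 6987 and 4144 CPM in WT and 3875 and 3544 CPM in Mut-labelled libraries, and without that library the median there was -0.23. The median interaction was -1.18 (SE 0.09 over genes, which share the same libraries). In the fit without a block, 18 genes had an unadjusted p below 0.05 and 0 passed after adjustment (edgeR). With a block per sorted sample, 15 listed genes were called. Clu stood at 381, 387, 654 and 577 CPM in WT replicates 1 and 2 and Mut-labelled replicates 1 and 2 of the mRNA libraries, and at 1775, 980, 1044 and 890 CPM in the total RNA libraries.

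Epithelial cells among the sorted cells would give both kinds of library the same difference if both came from 1 sorted sample. That was read from shared names. Under this reading the median interaction of -1.18 argues against such cells as the whole source. From group means it stayed between -0.78 (without the total RNA library of WT replicate 1) and -1.53 when single libraries were left out. A single outside source of RNA or reads that entered after the split would move all these genes alike within a kind. The SD over genes of the log2 fold change was at most 0.139. A single source present before the split would also give a small SD, so it does not tell when a source entered. RNA carried over and reads of another library were not tested. An effect of the genotype stays open as untested.

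The 380 genes that followed these transcripts were taken by a broad rule, a level higher in WT total RNA than in WT mRNA libraries by at least 1 on the log2 scale and an interaction of at most -0.5. It selects on the difference between the kinds itself, so that directions among these genes are no evidence of a source, and it also takes histone genes without a polyA tail and genes such as She, Sox5 and Qrfp. Among them, 28 were called higher and 0 lower in mRNA libraries, and 9 higher and 17 lower in total RNA libraries. Genes expressed in the sorted cells as well as in such a source are not removed by this rule.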

How the results depend on the processing

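The removal of immunoglobulin genes, the removal of genes that follow epithelial transcripts and ERCC scaling with the replicate block were chosen after seeing the data. Between WT and Mut-labelled mRNA libraries, 624 calls became 170 with ERCC scaling, 1615 with DESeq2, 1338 with the edgeR exact test and 128 at an adjusted p under 0.01. RLE, upper quartile, totals, either filter, voom, 1 fit over all libraries, a fold minimum and removal of genes gave 553 to 914, and leaving out a library 602 to 815. In total RNA libraries 445 became 724 with no filter, 199 with DESeq2, 273 with 1 fit over all libraries and 248 at an adjusted p under 0.01, the other settings gave 321 to 503, and leaving out a library gave 386 to 598. The labels do not say what same-numbered samples share beyond the number. The correlation of their deviations from group means was 0.323 in mRNA and 0.220 in total RNA libraries. With the replicate block 2870 genes were called in mRNA libraries and 870 in total RNA libraries, and 3 list calls changed (camera): ribosome biogenesis factors in total RNA (adjusted p = 0.0516) and histones in mRNA libraries (0.0546) were not called, and nuclear oxidative phosphorylation genes in mRNA libraries were called lower (0.0353). With a block per sorted sample the interaction had 111 calls, against 0 to 1 without a library. ERCC scaling with the block gave 7752 calls (604 higher, 7148 lower) and 8815 calls (79 higher, 8736 lower), with medians of all genes of -0.42 and -1.12. Of 17128 and 10546 genes tested, these calls held 621 of the 624 main calls in mRNA and 256 of the 445 in total RNA libraries. Values of single genes and lists are not given for that setting, a choice made after they were seen. Under it 0 of 58 named genes turned sign in mRNA and 5 of 57 in total RNA libraries.

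Of 58 called named genes in mRNA libraries, 51 kept their call without each library in turn, and of 57 in total RNA libraries, 40. None turned sign. ERCC scaling kept 17 and 28 calls, and in total RNA libraries turned Runx3 (-0.47), Apaf1 (-0.26), Csf3r (-0.20), Hist1h2ac (-0.30) and Prkcq (-0.22). Runx1 kept its sign in every setting and its call without each library (log2 fold change 1.88 to 2.21 in mRNA, 1.81 to 1.95 in total RNA libraries), but not its call under ERCC scaling (1.73, edgeR adjusted p = 0.999, and 0.78, adjusted p = 0.257). Voom lost 9 and 4 named calls and DESeq2 0 and 18.

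Of the list calls, 13 in mRNA and 11 in total RNA libraries, camera with an estimated correlation left 0 and 0, fry 0 and 1, and fry with ERCC scaling 0 and 0. Ribosome biogenesis factors then had an adjusted p of 0.976, 0.648 and 0.857 in mRNA and 0.811, 0.431 and 0.243 in total RNA libraries. Calls were also lost where the estimated correlation was negative, as for erythroid genes in total RNA libraries (-0.141, camera adjusted p = 0.324). With 2 residual degrees of freedom that setting could call few lists, so its lost calls do not show that correlation made them. Fry with ERCC scaling turned the direction of the Runx family, p53 targets and granulocyte-monocyte progenitor genes in mRNA libraries (adjusted p = 0.943 each). In total RNA libraries it turned granulocyte-monocyte progenitor (0.344), megakaryocyte (0.918), mast cell (0.243), NF-kB (0.243), immediate early (0.243) and histone (0.286) genes. Without each library in turn, the camera adjusted p of ribosomal proteins in mRNA libraries was 4.9e-04 (without WT replicate 2) to 0.363 (without Mut-labelled replicate 2), and of ribosome biogenesis factors 7.1e-06 (without WT replicate 2) to 0.633 (without WT replicate 1). In total RNA libraries these were 0.225 to 0.802 and 0.0333 to 0.514, and 5 (without WT replicate 1) to 13 lists were called, against 11 to 18 in mRNA libraries. Ratios to ERCC counts moved within the spread of replicates, with 0.474 to 1.22 for mRNA, 0.350 to 0.618 for total RNA and 0.296 to 0.636 for rRNA. The cause was not tested for any of these changes, and the lower depth of the total RNA libraries limits the genes that could be tested there.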

Other observations

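Genes of the constant parts of antibodies and of the chain that joins antibodies were chosen after their values were seen. Ighm, the heavy chain gene of IgM and of early B cells, fell by 3.23 in mRNA libraries (SE 0.38, edgeR adjusted p = 0.0152) and by 2.82 in total RNA libraries (edgeR adjusted p = 6.2e-06). Igkc, the kappa light chain gene, and Jchain, which joins antibody units in plasma cells, had log2 fold changes of -2.14 (SE 1.21) and -1.93 (SE 1.31) and were not called in mRNA libraries (edgeR adjusted p = 0.51 and 0.61). Jchain stood at 205 and 2606 CPM in WT and 86.7 and 651 CPM in Mut-labelled libraries. The 89 variable genes summed to 223 and 2600 CPM in WT and 112 and 892 CPM in Mut-labelled mRNA libraries.

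For the lower variable genes the plasma cell test was chosen before its result was seen and the test on clones after, and neither decided. Fewer plasma cells in the Mut-labelled samples could lower other plasma cell genes, although a lineage-negative sort such as LSK may remove these cells. The median log2 fold change of 8 genes with a level under 5 CPM in at least 1 library was -1.21 (SE 0.22 over genes). For all 8 that lowest library was a Mut-labelled one, so that the choice of genes favoured a fall and the test is void; the genes it left out, Creld2, Sdc1, Xbp1, Txndc5 and Jchain, stood at 0.13, 0.28, -0.19, -0.54 and -1.93, and Sdc1 was among the genes that followed epithelial transcripts. Of the variable genes separated between groups 28 were lower and 1 higher, a share of 0.966 (95% interval 0.822 to 0.999), but a draw of few clones would also lower most of them. The largest variable gene took 39.9 and 28.2% of variable gene CPM in Mut-labelled and 9.1 and 7.53% in WT libraries, so that fewer plasma cells, chance clones and the genotype cannot be told apart.

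For the lower counts per ERCC count in total RNA libraries the tests were chosen after the result was seen. An unequal spike-in amount set once per sorted sample before the split would shift both kinds of library alike. The log2 quotients of total RNA over mRNA values were 0.65, -0.85, 0.21 and -1.84, and their group means differed by -0.72, less than the Mut-labelled replicates did (2.05), so that it stays open. Spike-in recovery that varied from library to library could not be excluded, since the difference between groups was 1.68 times the larger difference between replicates. An effect of the genotype on RNA per cell likewise stays open with 2 libraries per group. Spike-in RNA added to purified RNA cannot show differences in RNA lost before it.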
